A study of Danio rerio with 10 samples.

How the data were processed

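Gene expression in zebrafish embryos was measured on 10 Affymetrix Zebrafish Genome Arrays with 1 channel each, in 2 experiments. In experiment 1, embryos given a morpholino against sox19b were compared with control embryos at 4.3 h post fertilization (hpf), with 3 arrays per group. A morpholino is an antisense oligonucleotide; this one was aimed at an intron-exon junction and so acts on splicing. The labels call the control arrays wild type, whereas the series text describes a placebo injection, and they are named control here. In experiment 2, wild type embryos at 2.5 hpf, before the mid-blastula transition, were compared with wild type embryos at 4 hpf, after it, with 2 arrays per group. The mid-blastula transition is the stage at which the embryo's own genome becomes widely transcribed and many transcripts laid down in the egg are cleared. Per the labels, total RNA was purified with Trizol and RNeasy columns and labelled as biotinylated cRNA. The parents of each batch of eggs are not given in the sources used here, so no p-value here measures more than the spread between these samples.

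The deposited values are log2 expression values per probe set, which the authors made with the affy package and robust multi-array average (RMA: background correction, normalization between arrays and summary of each probe set); the versions of both are not given. The values were used on that log2 scale without further normalization. The sorted values of any pair of arrays differed by at most 0.362 within experiment 1 and by at most 0.194 within experiment 2, but by up to 1.52 between the experiments. The experiments were therefore treated as normalized apart, and levels were compared across experiments only after joint quantile normalization or against control probe sets. Where deposited values of both stand side by side, as for sox19b, their levels are not compared. Correlations between arrays of both experiments used the deposited values. Array medians lay between 5.40 and 5.44 in experiment 1 and between 6.16 and 6.26 in experiment 2. Arrays give no counts, so the number of arrays limits the precision. As a reference for background, 17 tag control probe sets with no zebrafish target were used. The highest mean among them was 5.10 in arrays labelled morphant, 5.13 in control arrays, 6.24 at 2.5 hpf and 6.33 at 4 hpf, and a probe set at or below that value in a group was called dim in that group. A fold change against a dim group is given as a lower bound, computed against this value.

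Of 15617 probe sets, 115 AFFX control probe sets were left out and 15502 were tested. The array annotation gave 1 gene for 10795 of them, several genes for 135 and none for 4572, which came to 8793 different genes. Of the probe sets with 1 gene, 10711 were matched by Entrez identifier to a RefSeq gene table of the assembly GRCz12tu, used for names only, and 1 symbol was replaced. No genome sequence was used, so the positions of probes within genes were not analysed here. Of 1539 genes with several probe sets, 14 were called in both directions in experiment 1 and 18 in experiment 2.

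Each experiment was fitted on its own with limma 3.58.1 (lmFit and eBayes, group as the only term, two-sided) in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A probe set was called, and is said to have risen or fallen, at a Benjamini-Hochberg adjusted p below 0.05 over all 15502 probe sets. Adjusted p-values of single genes are from limma throughout. The replicate numbers were checked for pairing: after each group's mean was removed, arrays of experiment 1 with the same number correlated at 0.318, 0.202 and 0.114, all above the threshold of 0.1, and those of experiment 2 at -0.024. A fit of experiment 1 with the replicate number as a block (paired) was run as an alternative and called 6920 probe sets instead of 6591.

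The link between the experiments was tested with limma's camera on the fit of experiment 1, for the probe sets with an adjusted p below 0.05 and at least a 2-fold rise from 2.5 to 4 hpf, and for those with at least a 2-fold fall. Where fewer than 50 probe sets passed, the 200 with the most extreme moderated t were to be taken instead; this applied to the fall, which 44 probe sets passed. No array is shared between the set's definition and its test. Overlaps of calls were tested with Fisher's exact test. A total of 19 gene lists holding 903 entries, of which 755 were measured, was tested in each experiment with camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the one with the highest mean over all 10 arrays) and Benjamini-Hochberg adjustment over the lists. Beside camera at the preset value, camera with an estimated inter-gene correlation and fry were run. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. Lists held 15 to 72 measured genes, and 54 genes are in more than 1 list.

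The comparisons, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule takes, from genes whose probe set maps to 1 symbol, the 8 largest rises and the 8 largest falls per comparison among called genes whose groups did not overlap. It adds up to 4 members of each list with the smallest p, the 6 genes of smallest p in arrays labelled morphant from each transition set, and sox19b, the other SoxB1 genes, pou5f3 and nanog. Symbols that are only clone names were left out where a named gene followed. Of the 8 largest rises in arrays labelled morphant, 1 is not reported here.

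The alternatives set at that point were the replicate block, all 10 arrays in 1 fit, centring each array on its median, quantile normalization of all 10 arrays, leaving out the 40% of probe sets with the lowest means, leaving out the 917 probe sets with the suffix s, x or a, eBayes with trend and robust settings, a further fold change threshold, 1 probe set per gene, the other set tests, and leaving out each array in turn. Added after seeing the data were centring on the 24 probe sets for Bacillus dap, thr, phe and lys, a lowered set held to at least 2-fold, and member counts without control replicate 2. The 10 splits of the 6 arrays of experiment 1 into equal groups were also run.

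The procedure was tested on simulated data with the same group sizes, in which 200 of 15502 probe sets were changed. At 3 against 3 arrays it recovered 19.4% of changes of 0.5 on the log2 scale, 74.6% of changes of 1 and 97.0% of changes of 2, with 7 false calls. At 2 against 2 arrays it recovered 17.9%, 80.6% and 98.5%, with 2 false calls. An unchanged list had a camera p of 0.746 and 0.861. The simulated noise was drawn independently for each probe set, so these data cannot check the inter-gene correlation that camera presets. Far fewer probe sets were changed than were called in either experiment.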

Results

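The data were expression values of 15502 probe sets on 10 arrays of whole zebrafish embryos. Experiment 1 held 3 arrays labelled morphant (embryos injected with a splice-blocking morpholino against sox19b) and 3 control arrays, all at 4.3 hpf. Experiment 2 held 2 arrays of wild type embryos at 2.5 hpf and 2 at 4 hpf. The values are log2 and were normalized by the authors, so a difference of 1 is a 2-fold change. Within experiment 1, arrays labelled morphant correlated with each other at 0.995 to 0.996 across probe sets. Control replicates 1 and 3 correlated at 0.996, and control replicate 2 stood apart from them at 0.990 and 0.992.

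The first comparison asks what differed in embryos labelled as given a morpholino against sox19b, which encodes a SoxB1 transcription factor that the egg supplies to the embryo. Sox19b protein was not measured. A morpholino that acts on splicing can act only on transcript that is not yet spliced, so it cannot be taken to remove spliced transcript supplied by the egg. The part supplied by the egg was not measured apart. The transcript of the targeted gene, sox19b, was higher in the arrays labelled morphant. The brighter of its 2 probe sets read 9.13, 8.80 and 9.18 in the arrays labelled morphant and 8.48, 7.63 and 8.09 in the control arrays. Its means were 9.04 ± 0.21 (SD, n = 3) and 8.07 ± 0.42 (SD, n = 3), a rise of 0.97 (SE 0.20, adjusted p = 0.00214). Its values in wild type embryos, normalized apart from these, were 8.47 and 8.38 at 2.5 hpf and 9.32 and 9.37 at 4 hpf. The other probe set read 8.55 ± 0.16 (SD, n = 3) in arrays labelled morphant and 7.22 ± 0.41 (SD, n = 3) in controls, a rise of 1.33 (SE 0.19, adjusted p = 1.82e-04). A splice-blocking morpholino need not lower the amount of transcript, and the place of these probes relative to the targeted junction was not analysed here, so these values do not measure the knockdown.

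Among the other SoxB1 genes, sox3 and sox19a were lower in the arrays labelled morphant. Sox3, by the brightest of its 3 probe sets, read 6.88 ± 0.43 (SD, n = 3) against 10.28 ± 0.28 (SD, n = 3) in controls, 10.5-fold lower (adjusted p = 7.18e-07). Another of its probe sets fell at least 4.75-fold, and the dimmest, at background in both groups, was not called (adjusted p = 0.0731), but was with the replicate number as a block (adjusted p = 0.0231; 0.0231 to 0.569 over all alternatives) and without labelled morphant replicate 3 or control replicate 2 (adjusted p = 0.0296 and 0.0481). Sox19a fell by 1.81 (adjusted p = 9.48e-06). Pou5f3, a POU factor of the early embryo, fell by 0.55 (adjusted p = 0.0029) from a high level of 11.67, and no longer passed when arrays were scaled on the Bacillus control probe sets (-0.31, adjusted p = 0.0542). Nanog, another maternally supplied pluripotency factor, read 11.40 and 11.41 (difference -0.01, adjusted p = 0.941). Of the 3 probe sets of sox2, 2 fell (adjusted p = 0.0327 and 0.027), with control replicate 2 at 7.07 and 6.10 and the other controls at 4.33 and 5.46, and 3.42 and 4.16. The brighter of these fell at least 1.43-fold, and the other was at background in both groups. Without control replicate 2 both were called (adjusted p = 0.0236 and 0.00315) but at background in both groups. Both calls were lost when any 1 array labelled morphant was left out, with adjusted p-values between 0.0634 and 0.114, and that of the brighter also without control replicate 3 (adjusted p = 0.0713). Under eBayes with trend and robust settings, with all arrays, neither was called (adjusted p = 0.192 and 0.179, the highest over the alternatives). The remaining sox2 probe set and the 3 of sox1a, all near background, were not called (adjusted p = 0.387, 0.87, 0.0791 and 0.58); without control replicate 2, 1 of the sox1a probe sets was (adjusted p = 0.0199).

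Across the array, many transcripts of the oocyte were higher and many of zygotic patterning and outer-layer genes lower in the embryos labelled morphant. Mos, a kinase of oocyte maturation, read 10.79 ± 0.05 (SD, n = 3) against 6.93 ± 0.34 (SD, n = 3) in controls, 14.5-fold higher (adjusted p = 8.09e-08). Keratin krt5 read 4.30 ± 0.50 (SD, n = 3) against 9.48 ± 0.11 (SD, n = 3), at least 20.9-fold lower (adjusted p = 8.05e-08). The T-box factor tbx16, which acts in mesoderm, read 6.42 ± 0.34 (SD, n = 3) against 10.97 ± 0.21 (SD, n = 3), 23.4-fold lower (adjusted p = 6.34e-08). Besides mos, the largest rises included those of rasef2 (at least 6.53-fold), the phosphatase gene pgp (3.55 on the log2 scale), the phosphatidate phosphatase gene lpin2 (3.28), hsd3b7 (3.26) and arl6ip1, which encodes a membrane protein of the endoplasmic reticulum (3.15). Besides tbx16 and krt5, the largest falls were those of the glycosyltransferase gene b3gnt5a, the actin-bundling gene lcp1, keratin krt97, the thymosin gene tmsb1, lrwd1 and the annexin gene anxa1a. Anxa1a fell by 4.47, and 6 of these 8 falls ended at background in arrays labelled morphant, with lower bounds between 6.51-fold and 24.8-fold.

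**Figure D1:**
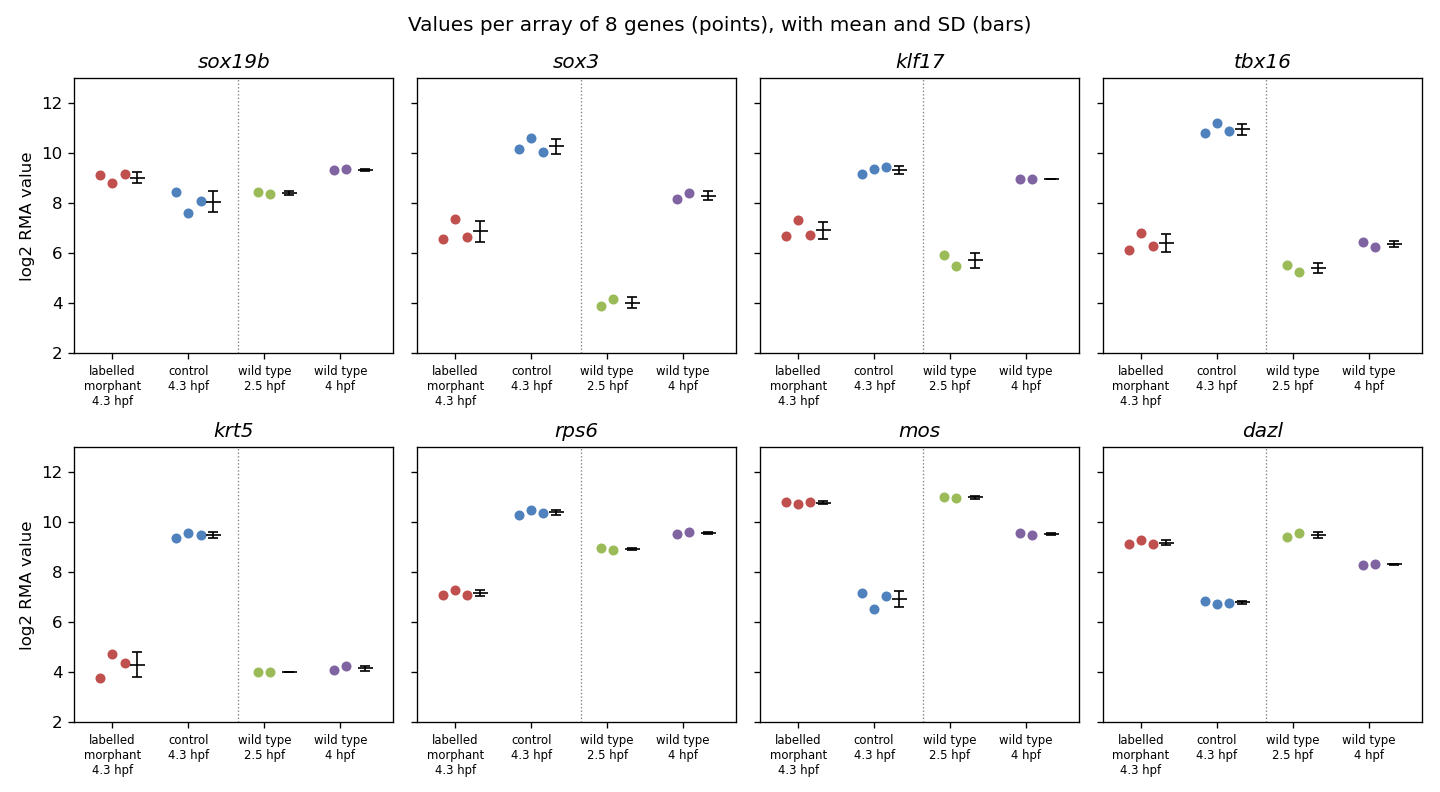
Log2 RMA values per array (points; bars give mean and SD) of 8 genes in the 4 groups; the dotted line parts the 2 experiments, which were normalized apart. Arrays labelled morphant lie above controls for sox19b, mos (10.79 against 6.93) and dazl, and below them for sox3, klf17, tbx16, krt5 and rps6.

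Zygotic gene groups were lower as groups. Of 44 measured first-wave genes (those known to be transcribed at the onset of zygotic transcription), 32 fell and 2 rose (32 and 3 adjusted over the list alone). Their median was -1.68, with tbx16, the retinoid-binding gene crabp2b (at least 1.45-fold lower) and the small heat shock gene hspb1 (-3.65) among them (camera adjusted p = 2e-11; adjusted p = 0.226 with an estimated correlation). Of 27 enveloping layer genes and keratins, which mark the outer cell layer, 21 fell and 1 rose (22 and 2 adjusted over the list alone), with sult6b1 at -3.22 and the calpain gene capn9 at least 9.49-fold lower (median -2.03, adjusted p = 2.14e-08; adjusted p = 0.226 with an estimated correlation). Of 31 BMP and ventral genes, 20 fell and 2 rose (22 and 2 adjusted over the list alone), with the ligands admp at -2.87 and bmp7a at -2.83 and the BMP inhibitor bambia at -3.76 (median -1.50, adjusted p = 1.85e-07; adjusted p = 0.25 with an estimated correlation). Of 30 Nodal and mesendoderm genes, 22 fell and 0 rose (22 and 0 adjusted over the list alone), with the receptor genes aplnra at -2.85 and cxcr4a at -3.35 and the endoderm factor foxa3 at -2.40 (median -0.91, adjusted p = 3.6e-09; adjusted p = 0.226 with an estimated correlation). Of 18 genes of the yolk syncytial layer, the nucleated layer under the blastoderm, 11 fell and 0 rose (12 and 0 adjusted over the list alone), with afp4 at -4.43 and the endodermal factors hnf4a, gata5 and gata6 (at least 6.74-, 7.80- and 2.13-fold lower) among them (median -0.76, adjusted p = 7.47e-06; adjusted p = 0.298 with an estimated correlation).

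Smaller signalling lists were also lower. Of 24 dorsal organiser and Wnt genes, 13 fell and 2 rose (13 and 3 adjusted over the list alone), with the Wnt receptor fzd7a at -2.19, the BMP antagonist chrd at -2.08 and the organiser factor gsc at -2.43 (median -0.65, adjusted p = 0.00108; adjusted p = 0.25 with an estimated correlation). Of 16 FGF genes, 10 fell and 2 rose (10 and 2 adjusted over the list alone), with the ligand fgf8a at -2.07, the receptor gene fgfr4 at -2.85 and the target etv4 at -2.07 (median -0.95, adjusted p = 0.00207; adjusted p = 0.226 with an estimated correlation). Of 15 SoxB1 and pluripotency genes, 8 fell and 2 rose (8 and 2 adjusted over the list alone), with sox3, klf17 (-2.41) and the Myc homologue mych (-2.84) among the falls and sox19b among the rises (median -0.55, adjusted p = 0.0101; adjusted p = 0.25 with an estimated correlation). Under Bacillus control scaling 5 of these 15 fell and 3 rose. Without control replicate 2, 32 first-wave, 20 enveloping layer, 20 BMP, 22 Nodal, 11 yolk syncytial layer, 13 dorsal, 10 FGF and 8 SoxB1 genes fell.

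Genes of ribosomes and of RNA processing fell together. Of 72 cytosolic ribosomal protein genes, 68 fell and 0 rose (70 and 0 adjusted over the list alone). Rps6 read 7.17 ± 0.12 (SD, n = 3) against 10.40 ± 0.10 (SD, n = 3), 9.37-fold lower, and rpl10a fell by 3.56. The list's median was -0.86 (adjusted p = 1.88e-21; adjusted p = 0.226 with an estimated correlation). Of 72 splicing genes, 51 fell and 1 rose (56 and 1 adjusted over the list alone), with the splicing regulators ptbp1a at -2.88 and srsf5a at -2.48 and the U2 component sf3a2 at -1.94 (median -0.52, adjusted p = 2.63e-12; adjusted p = 0.226 with an estimated correlation). Of 57 ribosome biogenesis and nucleolar genes, 36 fell and 6 rose (36 and 6 adjusted over the list alone), with nop14 at -1.82, nucleostemin gnl3 at -2.23 and wdr74 at least 1.30-fold lower (median -0.44, adjusted p = 1.96e-06; adjusted p = 0.226 with an estimated correlation). Without control replicate 2, 65 ribosomal protein, 45 splicing and 34 ribosome biogenesis genes fell, and under Bacillus control scaling 55, 34 and 21 did.

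The maternal oocyte and germ plasm lists were higher. Of 35 maternal oocyte genes, 27 rose and 2 fell (27 and 2 adjusted over the list alone), with mos and org (2.49) among them (median 0.87, adjusted p = 3.04e-07; adjusted p = 0.301 with an estimated correlation). The claudin gene cldng counted among these rises by its brightest probe set (2.52), whereas its other 3 probe sets fell (2 of them at -1.79 and -2.48). Of 17 germ plasm genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone), with median 0.83 (adjusted p = 0.00735; adjusted p = 0.325 with an estimated correlation). The germ cell RNA-binding gene dazl read 9.20 ± 0.09 (SD, n = 3) against 6.80 ± 0.07 (SD, n = 3), 5.26-fold higher, and the germ cell genes tdrd6a and dnd1 rose by 2.36 and 1.73. The 1 germ plasm gene that fell was the chemokine receptor gene cxcr4b (-2.80). Without control replicate 2, 27 maternal and 10 germ plasm genes rose.

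Other lists held changed genes in both directions and were not called by camera. Of 69 cell cycle and replication genes, 23 rose and 19 fell (25 and 22 adjusted over the list alone), with survivin birc5b at 2.42, ccnd1 at -3.24 and the helicase gene mcm3 at -2.76; the median was 0.09 and the mean -0.01 (adjusted p = 0.837). Of 69 oxidative phosphorylation genes, 22 rose and 16 fell (24 and 16 adjusted over the list alone), with ndufb5 at 1.52 and ndufb8 at -0.95 (adjusted p = 0.567). Of 29 stress response genes, 10 rose and 8 fell (10 and 8 adjusted over the list alone), with hsp90aa1.2 at least 2.69-fold lower and gstp1.2 at 1.36 (adjusted p = 0.979). Of 28 p53 target and apoptosis genes, 6 rose and 9 fell (6 and 9 adjusted over the list alone), with the p53 regulator mdm4 at 2.60 and sesn3 at -3.51 (adjusted p = 0.262). Of 44 neural plate genes, 9 rose and 13 fell (9 and 13 adjusted over the list alone), with zic2b at -3.78 and sox11a at -3.04 (adjusted p = 0.135). Of 58 genes of late differentiated tissues, 5 fell and 0 rose (2 and 0 adjusted over the list alone), among them lcp1 and the neuronal gene stmn2a, the latter dim in both groups (adjusted p = 0.122). The medians of the stress, p53, neural and late lists were -0.04, -0.14, -0.09 and -0.07 and turned positive under Bacillus control scaling. Under that scaling the counts of rises and falls were 38 and 13 for cell cycle, 36 and 9 for oxidative phosphorylation, 13 and 7 for stress, 11 and 8 for p53, 14 and 10 for neural plate and 10 and 2 for late tissue genes.

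In all, 6591 of 15502 probe sets (42.5%) were called between arrays labelled morphant and control arrays: 3307 rose and 3284 fell, in 2289 and 1894 genes by their brightest probe set. At least 2-fold, 1329 rose and 1031 fell, and at least 4-fold 218 and 362 did. Camera called 13 of the 19 lists, 2 higher and 11 lower, and with an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, while fry called 15. The split by direction rests on the scaling: on the Bacillus control probe sets the median of all probe sets moved from -0.04 to 0.21, and 5704 rose and 1970 fell. The 13 called lists kept the sign of their medians under that scaling, median centring and joint quantile normalization.

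The second comparison asks which transcripts changed across the mid-blastula transition in wild type embryos. By camera at the preset correlation the list of first-wave zygotic genes was higher at 4 hpf than at 2.5 hpf (29 of 44 rose) and that of maternal oocyte genes lower (10 of 35 fell). Camera with an estimated correlation called neither (adjusted p = 0.229 and 0.248). Sox3 read 4.03 ± 0.22 (SD, n = 2) at 2.5 hpf, which is background, and 8.32 ± 0.17 (SD, n = 2) at 4 hpf, at least 4.22-fold higher (adjusted p = 2.59e-10). Mos read 11.04 and 10.97 at 2.5 hpf and 9.58 and 9.51 at 4 hpf, 2.74-fold lower (adjusted p = 3.76e-07). The egg-supplied sox19b also rose, by 0.93 (adjusted p = 2.36e-05) and, in its other probe set, by 1.60 (adjusted p = 1.41e-07).

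Further large rises were those of the homeobox genes irx7 (at least 4.42-fold) and mxtx2 (at least 3.53-fold), the latter a regulator of the yolk syncytial layer. The Krüppel-like factor klf17 rose at least 6.63-fold, inka1a at least 3.73-fold and the Hairy-related factor her5 at least 3.14-fold. The actin regulator marcksl1b, which was above background at both times, read 6.50 and 10.05, a rise of 3.55. Of the 8 largest rises, 7 started from background at 2.5 hpf. The largest falls were smaller: morc3a fell at least 1.93-fold and arl6ip1 by 1.85 on the log2 scale, and ano10b, the mitochondrial import gene timm21, the centriole gene stil (-1.43) and the cell cycle factor e2f5 (at least 2.24-fold) followed. Sox19a rose (adjusted p = 8.66e-06). Pou5f3 and nanog differed by -0.04 and 0.18 (adjusted p = 0.797 and 0.185), and sox2, at background at both times, was not called by the brightest of its probe sets (adjusted p = 0.292).

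Of 44 first-wave genes, 29 rose and 2 fell (31 and 2 adjusted over the list alone), with irx7, sox3, mxtx2 and klf17 among the rises (median 0.62, camera adjusted p = 3.07e-19; adjusted p = 0.229 with an estimated correlation). Of 15 SoxB1 and pluripotency genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with klf2a at least 1.58-fold higher (median 0.28, adjusted p = 2.44e-06; adjusted p = 0.248 with an estimated correlation). Of 30 Nodal and mesendoderm genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone), with cxcr4a at least 2.25-fold and the Nodal inhibitor lft2 at least 1.19-fold higher, and the notochord factor noto among the rises (median 0.26, adjusted p = 2.44e-06; adjusted p = 0.248 with an estimated correlation). Of 31 BMP and ventral genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone), with the ventral repressor vox at least 4.01-fold and admp at least 2.42-fold higher and the BMP target id1 at 2.22 (median 0.18, adjusted p = 5.14e-05; adjusted p = 0.248 with an estimated correlation). Of 44 neural plate genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone), with her5, sox11a (at least 1.14-fold) and zic2b among the rises (median 0.16, adjusted p = 5.14e-05; adjusted p = 0.248 with an estimated correlation). With median centring 8 and with joint quantile normalization 7 of these 44 rose. Of 24 dorsal organiser and Wnt genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with fzd8a at least 1.08-fold higher and the Wnt antagonist dkk1b among the rises (median 0.18, adjusted p = 0.00132; adjusted p = 0.248 with an estimated correlation).

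Cytosolic ribosomal protein genes were higher at 4 hpf: 29 of 72 rose and 1 fell (37 and 2 adjusted over the list alone), with rps2 at 0.71 and rps6 at 0.64 (median 0.24, adjusted p = 4.24e-08; adjusted p = 0.426 with an estimated correlation). With arrays centred on their medians 19 of them rose and 2 fell, and with joint quantile normalization 20 and 1. Of 72 splicing genes, 14 rose and 7 fell (22 and 7 adjusted over the list alone), with srsf5a and hnrnpa0b at 0.71 and lsm6 at -0.66 (median 0.14, adjusted p = 0.00555; adjusted p = 0.30 with an estimated correlation). That call was lost without wild type 4 hpf replicate 1 (adjusted p = 0.051). Lower lists were maternal oocyte genes, of which 10 of 35 fell and 1 rose (13 and 3 adjusted over the list alone), with mos, dazl (-1.17) and org (-0.51) falling and tdrd6a at 0.48 (median -0.19, adjusted p = 0.00114; adjusted p = 0.248 with an estimated correlation), and ribosome biogenesis genes. With median centring 16 and with joint quantile normalization 6 of the 35 fell. Of the 57 ribosome biogenesis genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone), with rrs1 at -0.62 and ppan at -0.53 (median -0.07, adjusted p = 0.0258; adjusted p = 0.426 with an estimated correlation).

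A further 3 lists were called higher on few members. Of 27 enveloping layer genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with sult6b1 and krt18a.1 among them (median 0.12, adjusted p = 0.00713; adjusted p = 0.384 with an estimated correlation). Of 18 yolk syncytial layer genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), namely mxtx2, the apolipoprotein gene apoeb (at least 3.7-fold) and the fibronectin gene fn1a (0.42) (median 0.17, adjusted p = 0.0032; adjusted p = 0.248 with an estimated correlation). Of 58 late tissue genes, 5 rose and 1 fell (2 and 0 adjusted over the list alone), with the muscle actin gene actc1b at 0.55 and the insulin gene ins at 0.36 (median 0.16, adjusted p = 0.00132; adjusted p = 0.44 with an estimated correlation); with median centring 2 and with joint quantile normalization 3 of these rose. Joint quantile normalization ended these 3 calls and that of ribosome biogenesis (adjusted p = 0.106, 0.114, 0.196 and 0.267). The ribosome biogenesis call was also lost without wild type 2.5 hpf replicate 1, wild type 4 hpf replicate 1 or wild type 4 hpf replicate 2 (adjusted p = 0.0714, 0.051 and 0.146).

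The remaining lists were not called by camera. Of 69 cell cycle genes, 8 rose and 19 fell (12 and 20 adjusted over the list alone), with the replication factor cdc45 at -0.93 and ccnd1 at least 1.41-fold higher (adjusted p = 0.0696). Of 17 germ plasm genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone), with cxcr4b at least 2.32-fold higher and dazl at -1.17 (adjusted p = 0.0501). Of 16 FGF genes, 4 rose and 2 fell (6 and 2 adjusted over the list alone), with the feedback phosphatase dusp6 at least 1.32-fold higher (adjusted p = 0.0599). With the replicate number as a block (paired), the FGF and germ plasm lists passed, at adjusted p = 0.0494 and 0.0476. Arrays of experiment 2 with the same number correlated at only -0.024. Camera with an estimated correlation and no block gave adjusted p = 0.426 and 0.434. Of 28 p53 target genes, 5 rose and 0 fell (6 and 1 adjusted over the list alone), with gadd45ga among the rises (adjusted p = 0.0696). Of 29 stress genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone), with hspb1 at least 1.61-fold higher and the chaperonin gene hspe1 at -0.79 (adjusted p = 0.252). Of 69 oxidative phosphorylation genes, 10 rose and 9 fell (11 and 12 adjusted over the list alone), with atp5mc3b at 0.67 and ndufs6 at -0.57 (adjusted p = 0.768). With median centring 3 p53, 3 stress and 4 oxidative phosphorylation genes rose and 2, 5 and 14 fell. With joint quantile normalization 3, 2 and 9 rose and 1, 4 and 7 fell.

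In all, 3030 of 15502 probe sets (19.5%) were called between 4 and 2.5 hpf: 1498 rose and 1532 fell, in 779 and 1037 genes by their brightest probe set. At least 2-fold, 127 rose and 44 fell, and at least 4-fold 41 and 2 did. Camera called 13 lists, 11 higher and 2 lower; with an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, and fry called 10. Without wild type 2.5 hpf replicate 2 the count was 1426, and with all 10 arrays in 1 fit it was 734. The split rests on the scaling, since with each array centred on its median 754 rose and 2302 fell. Sox19a, zic2b, noto, dkk1b, sult6b1, krt18a.1 and gadd45ga were at background at both times, so no fold is given for their rises.

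**Figure D2:**
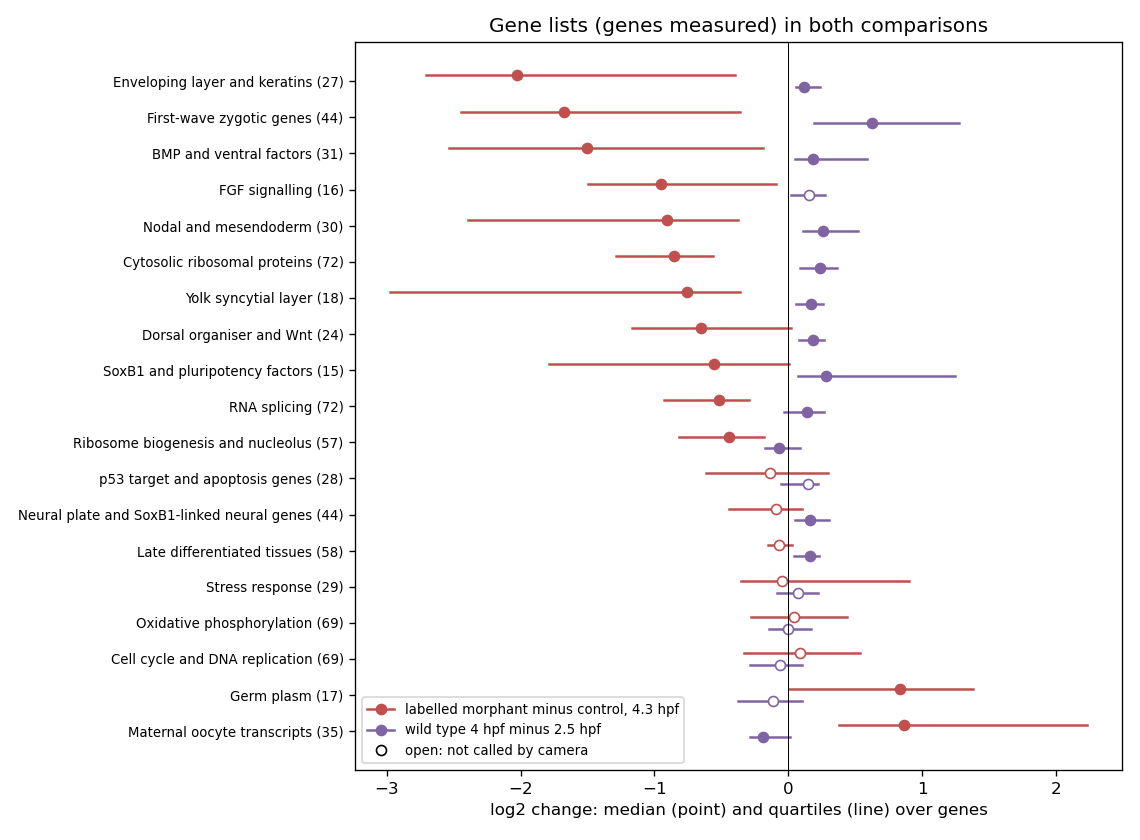
Median log2 change (points) and quartiles (lines) over the measured genes of each of 19 lists, for arrays labelled morphant minus control and for wild type 4 hpf minus 2.5 hpf; open points mark lists that camera did not call. Enveloping layer, first-wave and BMP genes had the lowest medians in arrays labelled morphant (-2.03, -1.68 and -1.50) and maternal oocyte genes the highest (0.87).

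The third comparison asks whether genes that change across the transition differ in embryos labelled morphant at 4.3 hpf. Most probe sets raised at least 2-fold in wild type embryos were lower in arrays labelled morphant, and most of those with the most extreme falls were higher. Of the 127 probe sets raised at least 2-fold, 106 fell, 6 rose and 15 were not called. Their median was -1.66 (camera p = 6.34e-29; p = 0.0243 with an estimated correlation). Among them were the finTRIM gene ftr82, which read 5.93 ± 0.22 (SD, n = 3) against 9.73 ± 0.04 (SD, n = 3), mplkip (-3.27), the BMP-family ligand admp (-2.87) and the neural plate factor zic2b (-3.78). Of the 200 probe sets with the most extreme fall by moderated t, 160 rose and 8 fell, with a median of 1.17 (camera p = 9.56e-31; p = 0.0028 with an estimated correlation). Among them were arl6ip1 (3.15), the cytokinesis gene ect2 (3.14), mos (3.85), dazl (2.40) and the methyltransferase gene trmt9b (3.10). Without wild type 4 hpf replicate 2 the set became the 51 probe sets lowered at least 2-fold, with a median of 1.77. Of the 44 probe sets lowered at least 2-fold, 41 rose and 1 fell, with a median of 1.85.

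**Figure D3:**
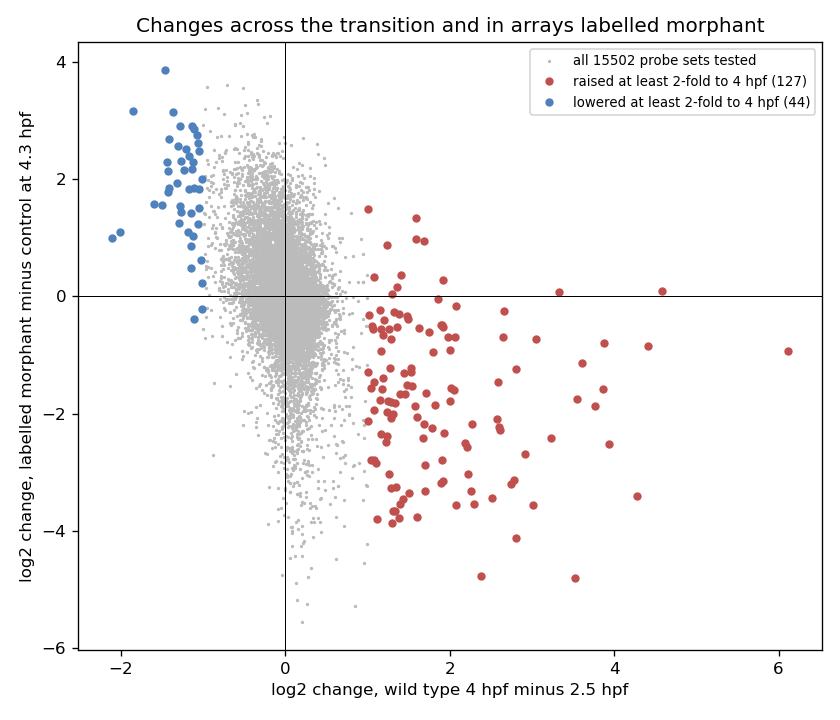
Log2 change from 2.5 to 4 hpf in wild type embryos (horizontal axis) against log2 change in arrays labelled morphant minus control (vertical axis) for 15502 probe sets (grey points). Of the 127 probe sets raised at least 2-fold (red), 106 fell in arrays labelled morphant, and of the 44 lowered at least 2-fold (blue), 41 rose.

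Of all 1498 probe sets that rose to 4 hpf, 579 (38.7%, against 21.2% of all probe sets) fell in arrays labelled morphant, where independence gives 317 (odds ratio 2.63, 95% interval 2.35 to 2.95, Fisher's exact p = 1.29e-59), and 162 rose, where independence gives 320. Of the 1532 that fell to 4 hpf, 915 (59.7%, against 21.3%) rose in arrays labelled morphant, where independence gives 327 (odds ratio 7.18, Fisher's exact p = 9.23e-266). Fisher's exact test treats probe sets as independent replicates, which they are not, so its p-values and interval do not measure the spread between samples. Of 1816 probe sets called in both comparisons, 1494 (82.3%) changed in opposite directions and 322 in the same direction. A further 4775 probe sets were called in experiment 1 alone. Not every gene went the opposite way: sox19b rose in both, and nanog was called in neither of the main fits. Nor did every list, although first-wave and maternal oocyte genes did. Camera at the preset correlation called ribosome biogenesis genes lower in both comparisons, with medians of -0.44 in arrays labelled morphant and -0.07 from 2.5 to 4 hpf. The latter call was lost under joint quantile normalization. Across the 15502 probe sets the changes of the experiments correlated at r = -0.402; this is a correlation across probe sets, which are not independent replicates. Without control replicate 2, 108 of the 127 raised probe sets fell and 158 of the 200 lowered ones rose, and under Bacillus control scaling 97 and 173 did.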

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

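The tests in this part were chosen only after the results were seen, apart from the scalings by median centring and joint quantile normalization, which were planned.

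Probe sets for Bacillus dap, a gene that zebrafish lack, had a median log2 value of 7.41 in the control arrays, above the brightest tag control at 5.13, which is a signal outside the main measurement. Over all 24 Bacillus probe sets (dap, thr, phe and lys) the median difference of arrays labelled morphant from controls was -0.27, with lower means in 24 of 24, and from 2.5 to 4 hpf it was 0.01. Against the control mean, the median of the 18 hybridization control probe sets was -0.32, -0.42 and -0.11 in the arrays labelled morphant and -0.16, 0.03 and 0.08 in the controls, so these values do not separate an amount of RNA from the processing of the arrays. Whether these RNAs were added to the samples, and in what amount, is not given in the sources used here.

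Genes raised from 2.5 to 4 hpf were lower, and genes lowered over that interval higher, in arrays labelled morphant at 4.3 hpf. Under all 3 other scalings the size of both medians was 1.38 or more, the lowered set then holding 73, 83 and 200 probe sets. With the sets of 127 and 200 taken from the deposited values it was 1.08 or more. Median centring and joint quantile normalization could change little here. Array medians of experiment 1 already lay between 5.40 and 5.44, and sorted values differed by at most 0.362. Centring moves all probe sets of an array alike, so an offset between arrays cannot both lower the raised set and raise the lowered set. An offset was argued against as the whole cause by these opposite signs, and the rescaling adds little to that. A candidate explanation is that the embryos labelled morphant were at an earlier stage than the controls. The 2360 probe sets that differed at least 2-fold were set against wild type after joint quantile normalization. Arrays labelled morphant lay nearer than controls to wild type at 4 hpf in 83.1% of them (87.9% to wild type at 2.5 hpf). Of all probe sets 63.2% did so at 4 hpf. That share includes probe sets that hardly differ between the groups. It is therefore not a like reference for probe sets picked for a large difference. In the raised set 81.1% did so, but in the lowered set, at 63.5%, no more than among all probe sets. Deposited values of arrays labelled morphant correlated with wild type at 4 hpf at 0.947 to 0.952, those of controls at 0.874 to 0.902. With wild type at 2.5 hpf these were 0.941 to 0.945 and 0.848 to 0.880. Whether the embryos labelled morphant or the controls departed from their stated age was not tested. Activation of p53, a known side effect of morpholinos, could not be decided from 5 target genes, whose median was -0.21; 2 of them (mdm2 and phlda3) fell and 0 rose. A need for Sox19b in the transition stays open and untested, since it and a difference in stage would both lower zygotic and raise maternal transcripts, and this design cannot separate them.

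Control replicate 2 stood apart from the other control arrays. RNA of embryos labelled morphant mixed into it was argued against, because it deviated away from the arrays labelled morphant in 69.2% of the 6356 probe sets called without it. A later stage of this sample may contribute but stays open, because its median deviation was 0.040 over the genes raised from 2.5 to 4 hpf and -0.073 over those lowered, too small to decide. No biological explanation was tested, since the labels name no difference between the control samples.

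The transcript of sox19b, the targeted gene, was higher in arrays labelled morphant. A single misreporting probe set was argued against, because the second probe set rose by 1.33. Scaling between arrays was argued against as the whole cause, because the smallest rise under the 3 other scalings was 0.88. Median centring could change little here, since the array medians of experiment 1 already lay between 5.40 and 5.44. Exchanged labels of the 2 groups cannot be told apart from correct ones by the rise of 0.97, because a splice-blocking morpholino may lower, leave or raise the amount of transcript. The closer correlation of arrays labelled morphant with wild type at 4 hpf (0.947 to 0.952, against 0.874 to 0.902 for controls) bears on this as well. Exchanged labels and a difference in stage could both give it, and these values do not separate them. A response of the sox19b transcript to the morpholino stays open and was not tested. From 2.5 to 4 hpf both probe sets rose in wild type embryos, by 0.93 and 1.6. An earlier stage of the embryos labelled morphant within that interval would therefore go with lower, not higher, sox19b. Wild type embryos after 4 hpf were not measured, so a difference in stage beyond that time stays open.

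Samples of 3 against 3 make only 10 splits, too few for a share under 0.05. The real split gave 6591 called probe sets and the highest other split 0. For the raised set, the size of the median was 1.66 in the real split and 0.727 in the highest other. For the lowered set it was 1.17 and 0.465. For the gene lists, 13 were called in the real split and 13 in the highest other, and 3 of the 10 splits gave as many. The labels name no pairing, but the replicate numbers of experiment 1 passed the correlation threshold of 0.1. If they are taken as pairs, the highest values among the other 3 splits that part all 3 pairs were 0 probe sets, 0.627, 0.418 and 13 lists. Every other split mixed both labels within its groups, so part of the difference between the labels stayed in the comparison. That difference also widened the spread within groups. The values of the other splits therefore do not measure chance alone.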

How the results depend on the processing

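No called gene, list called by camera or transition set of the report turned its direction (the gene families counted by symbol are not included). The p53 and neural plate lists, which in arrays labelled morphant were called by fry but not by camera, had medians that turned positive under Bacillus control scaling. Scaling on the Bacillus probe sets and holding the lowered set to 2-fold were chosen after seeing the data, and the other alternatives were planned. The rise of sox19b (0.75 to 1.17 with single arrays left out), the fall of the raised set (-1.78 to -1.54) and the rise of the lowered set passed under every alternative run. The median of the lowered set was 1.15 to 1.19 where it held 200 probe sets with single arrays left out, and 1.68, 1.68 and 1.77 without wild type 2.5 hpf replicate 1, wild type 4 hpf replicate 1 and wild type 4 hpf replicate 2, where it became the 64, 54 and 51 probe sets lowered at least 2-fold. With the replicate number as a block (paired), 6920 probe sets were called in arrays labelled morphant and 3241 from 2.5 to 4 hpf. A fit of all 10 arrays called 734 from 2.5 to 4 hpf; the cause was not tested. With single arrays left out, 5676 to 6356 probe sets were called in arrays labelled morphant and 1426 to 2813 from 2.5 to 4 hpf, the fewest without wild type 2.5 hpf replicate 2; fewer arrays entered these fits, and a lone array was assumed to vary like the other group. A further 2-fold threshold left 2360 and 171, and 1 probe set per gene left 4227 in arrays labelled morphant, since fewer could pass. Camera with an estimated correlation called 0 lists in either experiment, against 15 and 10 by fry. The correlation between experiments was -0.354 after joint quantile normalization, -0.428 without dim probe sets, -0.421 with 1 probe set per gene and -0.415 to -0.383 with single arrays left out; the cause was not tested. A lowered set at 4-fold held too few probe sets to give a value. Over the named genes, 2612 results were called or not called as before, 70 lost and 8 gained a call, and over single lists these counts were 407, 38 and 11; results that were not called could turn their sign. Signal over background limits the folds of 6 of the 8 largest falls in arrays labelled morphant and of 7 of the 8 largest rises to 4 hpf.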

Other observations

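The gene families of the next paragraph were chosen by symbol after the data were seen, as were all counts in this part. After a first count, genes whose symbols match a family but whose products do not belong to it, such as zpr1, rab3ip and psmc3ip, were left out; no family gained or lost its call by this.

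Of 8 families, kinesins, zona pellucida genes, Hox genes and claudins have 2, 3, 1 and 5 genes in lists of the report, and the other families 0. Genes of the mitochondrial ribosome rose more often than they fell in arrays labelled morphant, whereas those of the cytosolic ribosome fell. Of 59 mitochondrial ribosomal protein genes, 30 rose and 9 fell in arrays labelled morphant, with mrpl12 at 1.98 and mrpl40 at 1.25 (median 0.35, or 0.60 under Bacillus control scaling; camera adjusted p = 0.0123; adjusted p = 0.334 with an estimated correlation). From 2.5 to 4 hpf, 17 of them fell and 3 rose (median -0.18, adjusted p = 5.4e-05; adjusted p = 0.582 with an estimated correlation). Of 16 nucleoporin genes, which encode the nuclear pore, 11 fell and 0 rose in arrays labelled morphant, with nup37 at -1.23 and nup85 at -0.87 (median -0.44, or -0.19 under Bacillus control scaling; adjusted p = 0.00742; adjusted p = 0.334 with an estimated correlation). Of 48 genes of the proteasome and its assembly factors, 20 fell and 4 rose, with psma4 at -1.92, psmb1 at -1.48 and psmg3 at 1.24 (median -0.21, which turned to 0.04 under Bacillus control scaling; adjusted p = 0.00742; adjusted p = 0.334 with an estimated correlation). Of 16 genes of zona pellucida proteins, the egg coat, 10 rose and 0 fell, with zp3d.2 at 1.45 and zp3f.1 at 1.32 (adjusted p = 0.0806). Kinesins (8 rose and 3 fell of 15, adjusted p = 0.162), with kif20a at 2.44, and Rab genes (13 rose and 4 fell of 36, adjusted p = 0.109), with rab20 at 2.06, were not called. Nor were claudins (4 rose and 6 fell of 24, adjusted p = 0.183) or Hox genes (2 rose and 1 fell of 42, adjusted p = 0.852), although from 2.5 to 4 hpf 5 Hox genes rose and 0 fell (median 0.14, or 0.05 with median centring and 0.03 with joint quantile normalization; adjusted p = 0.00325; adjusted p = 0.582 with an estimated correlation).

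Many genes that were lower in arrays labelled morphant were also at background in wild type embryos at 4 hpf. Of the 1031 probe sets at least 2-fold lower, 693 were dim at 4 hpf, each group set against its own experiment's tag controls. Of the 864 of them that were above background in controls, 60.9% were dim at 4 hpf, against 15.1% of all 8261 probe sets above background in controls. Keratin krt5, for example, was above the brightest tag control in the control arrays at 4.3 hpf (9.48 against 5.13) and below it in wild type at 4 hpf (4.16 against 6.33) and in arrays labelled morphant (4.30 against 5.10). Of the 1329 probe sets at least 2-fold higher, 80.4% lay nearer to wild type at 4 hpf in arrays labelled morphant than in controls after joint quantile normalization, and of the 1031 lower ones 86.5% did, against 63.2% of all probe sets. They lay nearer to wild type at 2.5 hpf as well, in 87.1% and 89.0%, against 66.0% of all probe sets. The shares of all probe sets include those that hardly differ between the groups. They are therefore not a like reference for probe sets picked for a 2-fold difference.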
